A study of Mus musculus with 6 samples.

How the data were processed

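The series holds 6 libraries of poly(A) RNA from fully grown mouse oocytes, 3 from WT and 3 from Nat10 conditional knockout females, collected 36 to 48 h after PMSG. Groups and replicate numbers were taken from the sample titles and genotype labels. Per the labels' protocols, the oocytes were lysed and their RNA was made into libraries by Smart-seq2, with oligo-dT priming and template switching followed by tagmentation. This protocol carries no molecular identifiers, so PCR copies are counted as separate reads, and no strand information.

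The authors deposited raw counts per gene for the 6 libraries, with coordinates and exonic lengths of 25239 gene symbols in the file header's layout of featureCounts. The submitters' processing notes name Trim Galore 0.6.7, STAR 2.7.10a, featureCounts (no version) and the mm10 build. How reads that map to several places or overlap several genes were counted, and with which strand setting, is not given in the sources used here. Genes with near-identical copies, such as ribosomal protein genes with pseudogenes, NLRP genes and the Usp17l family, and genes whose exons overlap another gene are therefore uncertain. Genes of the mitochondrial genome are not analysed here. A second deposited table gives, per library, the share of reads mapped and the share from ERCC spike-in RNA; its headings call them percent, its values are fractions of 1, and they were converted to percent here. The denominator of both shares was taken to be all reads, which the table does not state, and endogenous reads per ERCC read were computed as the mapped share less the ERCC share, divided by the ERCC share. Spike-in counts per species were not used here.

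Library totals ranged from 20167665 to 29407659 counts. Of the 25239 genes 5887 had no count in any library, and 14114 passed edgeR's filterByExpr (minimum count 10) and were tested. The main test was edgeR 4.0.16 (in R 4.3.3), with TMM factors, a quasi-likelihood F test of cKO against WT without a block, and Benjamini-Hochberg adjustment, two-sided, at 0.05. The biological coefficient of variation was 0.215. The standard error of a log2 fold change was computed as its size divided by the square root of F. CPM values use TMM-scaled totals. On counts simulated from these libraries' means for the 14114 genes, 200 genes were changed. The test recovered 22.4% of 67 genes changed 1.5-fold, 62.7% of 67 changed 2-fold and 78.8% of 66 changed 4-fold. Of its 121 calls 12 were false, a share above the 0.05 set for the adjusted p, in a single simulation. Far more genes were called in the real data, which makes the adjusted threshold less strict there, so these recoveries do not carry over.

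A total of 31 gene lists was written before the data were examined, and 30 had at least 5 tested members; the list of genes encoded by the mitochondrial genome had none. Lists were tested with limma 3.58.1's camera on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the 30 lists, and also with an estimated correlation and with fry. Camera asks whether a list stands apart from the other genes, while fry asks only whether its genes move one way on balance. The simulations of lists drew every gene independently, so they do not test the preset correlation. The correlation estimated from the real data was 0.573 for ribosomal protein genes and 0.369 for oxidative phosphorylation genes. In a simulation over 14114 genes with 1 list raised 1.4-fold, camera called that list and no other. With a length trend alone it called 4 lists, and 0 after the correction for length and GC content described next. That correction fitted, per library, a smooth trend of log2 CPM on log2 exonic length and GC content (mgcv 1.9.3) over genes outside the ribosomal protein and oxidative phosphorylation lists and removed it. Exonic lengths came from the count table, and GC content and codon shares from GENCODE M21 transcripts of the same build; 97.8% of symbols matched, and GC content was known for 99.1% of tested genes. The correlation of fold changes with codon shares, taken within bins of length and expression, was tested on simulated data too and gave -0.585 where a fall with C-ending codons was put in and -0.004 with a length trend alone. With a simulated GC trend alone it gave 0.403, and 0.036 once GC content was held in 5 bins each of length, expression and GC content.

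Genes named in the text followed a rule written before the data were examined. It took Nat10; the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose mean was at least 10 CPM in a group, leaving out predicted genes and pseudogenes; up to 4 called members per list with the smallest p, or the 2 most abundant where fewer than 2 were called; and, for markers of other cells, every called marker and the 2 most abundant. Not every gene of the rule is named. Single values per library were compared with exact permutation tests over the 20 assignments of 6 libraries. The alternatives were other normalizations (DESeq2's size factors, upper quartile, library totals, spike-in scaling), no or a stricter low-count filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, stricter thresholds and leaving out each library in turn. Spike-in scaling used each library's ERCC share to set the library size, and its p-values treat that scaling as known without error. The grouping of genes by expression uses the mean over all 6 libraries; it replaced a first grouping by the WT mean after that was seen, because splitting on 1 group biases the fold changes.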

Results

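Poly(A) RNA of fully grown mouse oocytes was profiled by Smart-seq2, a full-length cDNA method for very small amounts of RNA. The oocytes came from wild-type (WT) females and from females in which Nat10 was deleted with a Gdf9-cre driver, which is active in oocytes from early follicle stages (conditional knockout, cKO). They were collected 36 to 48 h after an injection of PMSG, a gonadotropin that stimulates follicle growth. NAT10 is the enzyme that writes N4-acetylcytidine on RNA, and the comparison asks how its loss changes the transcripts of the oocyte. Each genotype had 3 libraries. The WT libraries held 29407659, 22727643 and 20167665 gene counts and the cKO libraries 28623598, 28009591 and 26288767. At least 1 count was found for between 16012 and 17072 genes per library, and 3 counts, the limit that a count of 0 allows, corresponded to 0.102 to 0.149 CPM (counts scaled to library size), for counting error only. Nothing in the labels says that the 3 libraries of a genotype came from separate animals, nor how many oocytes each held, so the p-values measure the spread between these libraries, which may be partly technical.

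The targeted transcript was low in every library labelled cKO. Nat10 lies on the minus strand of chromosome 2, from 103721258 to 103761270 in mm10, and its counted exons span 3877 bases. It stood at 48.1, 45.01 and 64.5 CPM in the WT libraries and at 7.18, 7.65 and 7.99 CPM in the cKO libraries. The means were 52.5 ± 10.5 CPM (SD, n = 3) and 7.61 ± 0.41 CPM (SD, n = 3), or 14.5% of WT. The log2 fold change was -2.79 ± 0.19 (SE), with an adjusted p of 1.95e-06 in edgeR's quasi-likelihood test. The exons removed by the deletion are not named in the labels, so the remaining reads are a transcript level and not a protein level.

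**Figure D1:**
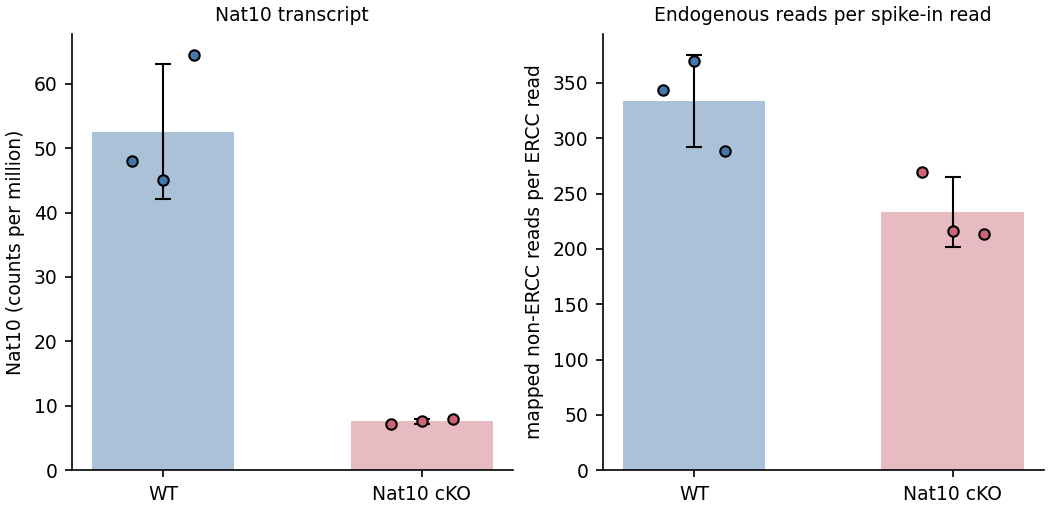
Nat10 in CPM (left) and mapped non-ERCC reads per ERCC spike-in read (right) in WT and Nat10 cKO oocytes, with bars for means, error bars for SDs of 3 libraries and points for single libraries. Nat10 fell to 14.5% of WT, and the 3 cKO libraries held between 214 and 270 reads per spike-in read against 288 to 370 in WT.

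A large part of the oocyte transcriptome differed between the genotypes. Of 14114 genes tested, 2836 rose and 2838 fell in cKO at an adjusted p under 0.05 in edgeR's quasi-likelihood test, together 40.2% of the genes. At least a 2-fold change was found for 1440 of the genes that rose and 1128 of those that fell. These counts are relative to the other transcripts of a library. After scaling by the spike-in RNA instead, 1183 genes were called higher and 4831 lower, since that scaling moved the median of all genes to -0.39 on the log2 scale, a shift that counts of every gene group carry. With library totals alone the median moved to 0.12 and the calls were 3450 higher and 2253 lower. The first principal component held 64.9% of the variance and separated the genotypes. Across genes, log2 CPM correlated at 0.972 to 0.980 between libraries of one genotype and at 0.917 to 0.947 between genotypes.

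Among genes with at least 10 CPM in a group, several of those that rose most were almost absent from WT oocytes. Slc6a3, the dopamine transporter gene on chromosome 13 (73536747 to 73578672), went from 0.16 ± 0.14 to 15.2 ± 5.5 CPM (SD, n = 3). Arl2bp, which encodes a partner of a small GTPase and lies on chromosome 8 (94666600 to 94674457), went from 0.90 ± 0.10 to 31.6 ± 12.7 CPM, a log2 change of 5.13 ± 0.33 (SE). The transketolase-like gene Tktl1 rose by 4.71 ± 0.37 on the log2 scale, the receptor gene Gpr83 by 4.25 ± 0.45, the SNARE gene Stx11 by 3.76 ± 0.41, and Ptgds, a prostaglandin D synthase gene, by 3.74 ± 0.20, from 3.88 to 52.0 CPM. AF067063 (5.63 ± 0.63) and Usp17lb (5.27 ± 0.91) were also among the 8 largest rises of such genes. Both have near-identical copies in the genome, so their values are uncertain, and in cKO replicate 2 Usp17lb reached 2.32 CPM against 40.7 and 25.8 CPM in the others; limma-voom no longer called it (adjusted p = 0.0827). Where WT is near 0 the fold is loosely fixed: without WT replicate 1 or 2 the log2 change of Slc6a3 was 5.97 or 7.41, without WT replicate 2 that of Gpr83 was 5.33, and that of Usp17lb was 6.44 without WT replicate 1 and 4.58 without cKO replicate 1.

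The 8 largest falls among genes with at least 10 CPM in a group included enzymes, a splicing factor and a signalling protein. Manba, the lysosomal beta-mannosidase gene on chromosome 3 (135485611 to 135571403), fell from 46.0 ± 25.6 to 1.23 ± 0.58 CPM (SD, n = 3). Cdc5l, a splicing factor gene on chromosome 17 (45391888 to 45433707), fell from 47.7 ± 12.7 to 1.499 ± 0.56 CPM, a log2 change of -4.98 ± 0.30 (SE). The carboxypeptidase gene Agbl2 changed by -4.73 ± 0.33, the glycosyltransferase gene Gcnt2 by -4.65 ± 0.52, the Golgi protein gene Tmem87a by -4.06 ± 0.18 (99.3 to 5.94 CPM), the chondroitin sulfotransferase gene Chst11 by -4.00 ± 0.33, Bpifc by -3.65 ± 0.47 and Plek, the pleckstrin gene, by -3.53 ± 0.34. Exons of Gcnt2 and of Tmem87a overlap a gene on the other strand (A730081D07Rik and Ganc). Smart-seq2 does not keep the strand, so reads from the overlapping stretch of such pairs cannot be told apart. The size of that stretch was not measured. Without cKO replicate 2 the log2 changes of Gcnt2 and Plek were -5.30 and -4.16.

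**Figure D2:**
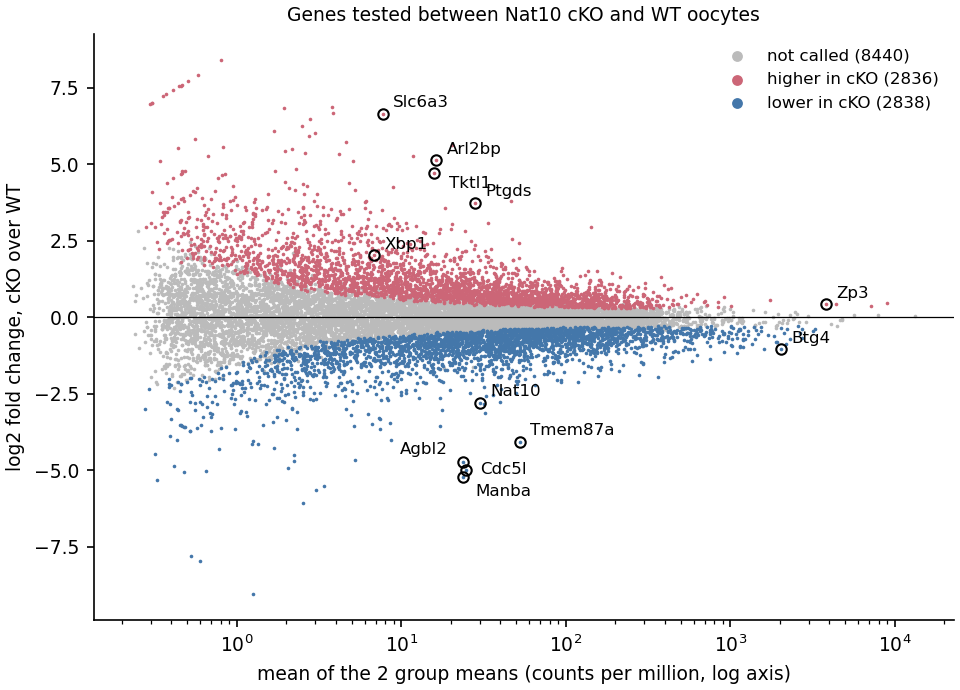
Log2 fold change (cKO over WT, vertical axis) against the mean of both group means in CPM (log axis) for the 14114 genes tested. Red points are the 2836 genes called higher, blue points the 2838 called lower and grey points the genes not called, at an adjusted p under 0.05 in edgeR's quasi-likelihood test; circles mark genes named in the text. After spike-in scaling the called genes were 1183 higher and 4831 lower.

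Genes for cytosolic ribosomal proteins rose together. Of 80 tested, 64 rose and 0 fell over all genes tested (65 and 0 adjusted over the list alone), with a median log2 fold change of 0.58 and an interquartile range of 0.39 to 0.78. After spike-in scaling the median was 0.16, with 8 called higher and 1 lower, and after a correction for transcript length and GC content it was 0.36, with 45 higher and 2 lower. Rpl12 went from 40.3 ± 5.8 to 94.9 ± 19.7 CPM (SD, n = 3), Rps3 from 102 ± 14 to 202 ± 20 CPM, and Rpl27 from 115 ± 17 to 227 ± 28 CPM. Of 73 nuclear genes for subunits of oxidative phosphorylation, 40 rose and 2 fell (43 and 2 adjusted over the list alone), with a median of 0.38 that was -0.03 after spike-in scaling (3 higher and 8 lower), where the median of all genes was -0.39. After the length and GC correction it was 0.15 (21 higher and 5 lower). Cyc1, the cytochrome c1 gene, rose from 31.4 to 88.5 CPM, and the ATP synthase subunit genes Atp5d and Atp5g3 rose by 1.18 ± 0.16 and 1.03 ± 0.16 (SE) on the log2 scale. Camera called these 2 lists among the 30 tested (adjusted p = 4.47e-12 and 1.94e-05 with a preset correlation), and called neither with a correlation estimated from the data (adjusted p = 0.764 for each). Both lists hold short transcripts, with median exonic lengths of 740 and 772 bases, and short transcripts were higher in cKO in general. Reads of ribosomal protein genes can be shared with their many pseudogenes, so single values in that list are uncertain. No list was called lower by camera; 3 lists were higher and 3 lower at an unadjusted p under 0.05, none in either direction with an estimated correlation, and fry called 7 higher and 6 lower.

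Other parts of the protein synthesis machinery moved in both directions, as did genes in general, of which 40.2% were called (2836 higher and 2838 lower). Translation factors and aminoacyl-tRNA synthetases held a smaller share of calls than that. Among 75 nucleolar ribosome biogenesis and RNA polymerase I and III genes, 26 rose and 13 fell (26 and 15 adjusted over the list alone), a majority that turned to 9 higher and 22 lower after spike-in scaling. Rrn3, an initiation factor of RNA polymerase I, fell to 37.6% of WT (log2 -1.41 ± 0.14, SE), while Nop10, a subunit of box H/ACA particles, rose by 1.10 on the log2 scale. Among 44 translation factors 13 rose and 3 fell (13 and 3 adjusted over the list alone; 3 and 11 after spike-in scaling), including Eef1b2 (2.14-fold higher) and Eif1a (2.72-fold higher). Among 22 aminoacyl-tRNA synthetases 3 rose and 4 fell (3 and 4 adjusted over the list alone; 0 and 8 after spike-in scaling, 4 and 3 with library totals alone, 4 and 4 after the length and GC correction). The isoleucine enzyme gene Iars fell to 53.4% of WT and the leucine enzyme gene Lars to 61.0%. The lysine enzyme gene Kars rose by 0.44 on the log2 scale, a call that ended after spike-in scaling (0.04) and without cKO replicate 1 (0.40, adjusted p = 0.0567). The median of that list was 0.06, whereas its mean and the direction of camera were negative.

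Maternal-effect and egg surface genes held more falls than rises, genes listed as germ-cell transcription factors more rises than falls except after spike-in scaling, and camera called none of these lists. Of all tested genes 40.2% were called. The egg surface list and the zona and secreted factor list held a share of calls near that, and the transcription factor list a smaller one. Of 29 maternal-effect genes, 12 fell and 4 rose (13 and 6 adjusted over the list alone; 16 and 0 after spike-in scaling, 11 and 9 with library totals alone, 17 and 5 after the length and GC correction). Sebox, a homeobox gene, fell from 150 ± 40 to 36.3 ± 4.6 CPM (SD, n = 3), Bnc1, the basonuclin gene, to 37.6% of WT, and the NLRP genes Nlrp9b and Nlrp4f to 39.2% and 49.3%; NLRP genes have close paralogs and their values are uncertain. Of 11 egg surface, fusion and cortical granule genes 5 fell and 0 rose (6 and 0 adjusted over the list alone; 8 and 0 after spike-in scaling, 4 and 1 with library totals alone). Among the genes that fell, Nlrp5 and Mfsd2a lost their calls when single libraries were left out. In edgeR's quasi-likelihood test their adjusted p was 0.0536 and 0.0874 without cKO replicate 1, and 0.0559 and 0.0666 without cKO replicate 3. Izumo1r, the Juno sperm receptor gene, fell from 653 ± 20 to 461 ± 39 CPM, and Rab27a, a small GTPase gene, fell to 55.9% of WT. Among 12 genes for zona pellucida proteins and oocyte-secreted factors 3 fell and 2 rose (4 and 2 adjusted over the list alone; 6 and 0 after spike-in scaling, 3 and 3 with library totals alone). The gap junction gene Gja4 fell to 51.5%, Fgf8 to 38.0% and Oosp3 to 57.7% of WT. Zp3, a zona protein gene, rose from 3264 ± 299 to 4380 ± 329 CPM, a log2 change of 0.42 that was no longer called after spike-in scaling (0.02) or after the length and GC correction (0.08). Of 17 genes listed as germ-cell transcription factors 5 rose and 1 fell (5 and 1 adjusted over the list alone), against 1 higher and 5 lower after spike-in scaling and 5 and 3 after the length and GC correction. Taf4b, a germ-cell TFIID subunit gene, rose from 22.6 to 41.2 CPM, no longer called after spike-in scaling. Gata4, which is listed there although it is known mainly from somatic cells of the ovary, rose from 20.3 to 46.3 CPM.

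Genes of mRNA decay and storage, whose transcripts are long (median exonic lengths of 3533 and 3464 bases), held more falls than rises, in a transcriptome where long transcripts were lower in general. Of 37 CCR4-NOT deadenylase and decay genes 12 fell and 4 rose (13 and 4 adjusted over the list alone; 20 and 2 after spike-in scaling, 9 and 6 with library totals alone or after the length and GC correction). That correction moved their median from -0.19 to -0.03. Both the decay and the storage list held a share of calls near the 40.2% of all tested genes. Btg4, the adaptor that recruits CCR4-NOT to maternal mRNA, fell from 2727 ± 234 to 1328 ± 206 CPM (SD, n = 3), a log2 change of -1.04 ± 0.12 (SE) with an adjusted p of 5.75e-05 in edgeR's quasi-likelihood test. The catalytic subunit gene Cnot7 fell from 659 ± 21 to 300 ± 63 CPM and Cnot2 to 58.6% of WT, while Lsm1, which acts in decapping, rose to 231%. Among 33 genes of mRNA storage and translational control 9 fell and 6 rose (9 and 6 adjusted over the list alone; 18 and 2 after spike-in scaling, 8 and 8 with library totals alone, 11 and 6 after the length and GC correction). That correction turned their median from -0.15 to 0.03. Pabpn1l, a germ-cell poly(A)-binding protein gene, fell to 43.2% of WT and the RNA-binding protein genes Bicc1 and Msi2 changed by -1.72 and -2.47 on the log2 scale, while Pabpc1 rose by 1.99.

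Genes of meiosis held calls in both directions, as did all genes tested, of which 40.2% were called. The spindle and actin list and the meiotic prophase list held a smaller share of calls than that. Of 44 genes of meiotic arrest, resumption and cell-cycle control 13 fell and 8 rose (14 and 8 adjusted over the list alone; 24 and 1 after spike-in scaling, 10 and 9 with library totals alone, 18 and 8 after the length and GC correction). The spindle checkpoint kinase genes Ttk and Bub1b fell to 35.7% and 52.2% of WT, Gpr3, a receptor that keeps oocytes in meiotic arrest, to 44.3%, and Fbxo43, an inhibitor of the anaphase-promoting complex, to 56.3%. Among 37 spindle and actin genes 6 fell and 5 rose (6 and 4 adjusted over the list alone), a balance that was 17 and 1 after spike-in scaling and 6 and 9 with library totals alone. The midzone gene Prc1 fell from 880 ± 19 to 374 ± 70 CPM (SD, n = 3) and Spire1 to 54.2% of WT, while Rac1 rose 2.47-fold. Of 29 meiotic prophase genes 6 rose and 3 fell (6 and 1 adjusted over the list alone; 4 and 11 after spike-in scaling). Dmc1, the meiotic recombinase gene, rose from 0.83 to 4.66 CPM, a log2 change of 2.45 that was 3.15 without WT replicate 1, and Stag3, a meiotic cohesin gene, rose 2.58-fold.

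Stress, damage and death genes went both ways as well. Against the 40.2% of all tested genes that were called, the apoptosis and proteasome lists held a smaller share of calls. Of 39 genes of the unfolded protein, integrated stress and heat-shock responses 12 rose and 7 fell (13 and 8 adjusted over the list alone), turning to 6 and 13 after spike-in scaling. Ddit3, the CHOP transcription factor gene, rose from 53.3 ± 9.4 to 138 ± 5 CPM (SD, n = 3), though its exons overlap Mars1 on the other strand, and Xbp1 rose by 2.04 on the log2 scale. The chaperone genes Hsp90aa1 and Hsp90ab1 fell to 45.7% and 46.8% of WT. Of 26 p53 and DNA damage genes 7 rose and 6 fell (7 and 6 adjusted over the list alone; 3 and 10 after spike-in scaling, 7 and 7 after the length and GC correction), with a median of -0.12, a mean of 0.02, and a direction that was down in camera and up in fry. Ccng1, a p53 target, rose 2.37-fold and Trp53inp1 fell to 48.8%. Of 26 core apoptosis genes 4 rose and 5 fell (4 and 5 adjusted over the list alone; 2 and 9 after spike-in scaling, 4 and 3 with library totals alone), among them the survival gene Mcl1 (4.62-fold higher) and the initiator caspase gene Casp2 (log2 change of -0.84). Of 50 RNA polymerase II and core splicing genes 17 rose and 4 fell (18 and 4 adjusted over the list alone), turning to 6 and 9 after spike-in scaling, and 14 and 7 after the length and GC correction. Polr2a, the largest subunit of RNA polymerase II, rose from 17.5 ± 7.8 to 54.5 ± 13.9 CPM, and the splicing factor gene Sf3b1 fell from 436 ± 37 to 151 ± 21 CPM. Of 33 proteasome subunits 5 rose and 4 fell (4 and 3 adjusted over the list alone; 1 and 10 after spike-in scaling, 9 and 3 with library totals alone, 3 and 7 after the length and GC correction), with Psmd13 2.35-fold higher and Psmd11 at 64.6% of WT.

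**Figure D3:**
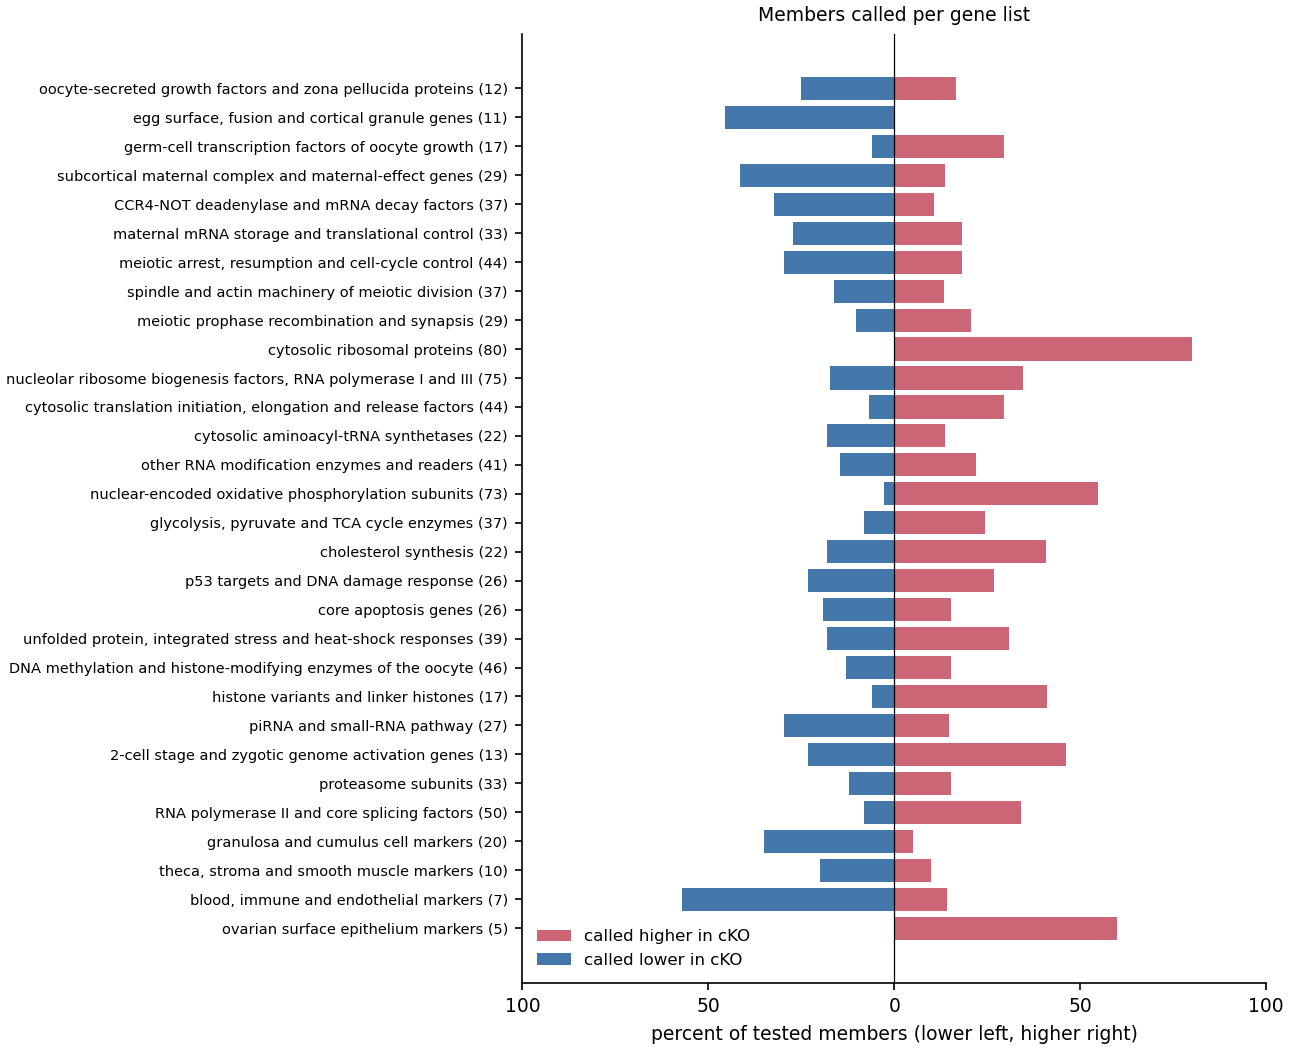
Percent of tested members of each gene list called lower (left, blue) or higher (right, red) in cKO, with the number of tested members in parentheses. The lists were fixed before the data were examined; 64 of 80 ribosomal protein genes and 40 of 73 oxidative phosphorylation genes were called higher; after spike-in scaling, which shifts all genes alike to a median of -0.39, 8 and 3 were higher and 1 and 8 lower, with list medians of 0.16 and -0.03.

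Most markers of other ovarian cells were at low levels, and several changed with the genotype. Of 20 granulosa and cumulus markers that could be tested 7 fell and 1 rose (7 and 1 adjusted over the list alone; 10 and 0 after spike-in scaling, 7 and 1 with library totals alone). Inha, an inhibin subunit gene, fell from 10.4 ± 2.7 to 3.93 ± 0.49 CPM (SD, n = 3), the gap junction gene Gja1 from 4.78 to 1.44 CPM, the estradiol-forming enzyme gene Hsd17b1 from 2.42 to 0.52 CPM and Akr1cl from 21.7 to 9.80 CPM. The most abundant markers of that list, Serpine2 (408 and 398 CPM) and Cyp19a1 (37.6 and 34.1 CPM), had log2 fold changes of -0.03 ± 0.12 and -0.14 ± 0.15 (SE). Of 7 blood and endothelial markers 4 fell and 1 rose (4 and 1 adjusted over the list alone, after spike-in scaling and with library totals alone). Flt1 and Kdr, receptors for vascular endothelial growth factor, fell from 7.51 to 1.51 and from 4.29 to 0.19 CPM, Tek from 14.8 to 7.29 CPM and the complement gene C1qb from 51.5 to 31.1 CPM. Without cKO replicate 2 the log2 change of Kdr was -5.83 against -4.49 with all libraries. Pecam1, the most abundant marker of that list, stood at 59.0 and 61.7 CPM and was not called. C1qa, a partner of C1qb, rose from 0.12 to 1.70 CPM, a log2 change of 3.79 that was 3.16 without WT replicate 1, 8.52 without WT replicate 2 and no longer called without cKO replicate 1 (3.26, adjusted p = 0.054). Of 5 surface epithelium markers 3 rose and 0 fell (3 and 0 adjusted over the list alone; 1 and 0 after spike-in scaling), among them Lrrn4, from 14.6 to 26.5 CPM, no longer called after spike-in scaling. The other risen markers, Upk3b and Krt7, lost their calls without cKO replicate 1 (adjusted p = 0.0513 and 0.0781 in edgeR's quasi-likelihood test). With 1 library left out, Krt7 kept its call only without WT replicate 1. Of 10 theca, stroma and muscle markers 1 rose and 2 fell (1 and 2 adjusted over the list alone; 0 and 2 after spike-in scaling), with a median of 0.12 and a mean of -0.27, and a direction that was down in camera and up in fry. All of these calls ended without WT replicate 1. There the adjusted p in edgeR's quasi-likelihood test was 0.0735 for Acta2 and 0.203 for Hsd3b1, which had fallen, and 0.0795 for Ogn, which had risen.

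Endogenous reads relative to reads of the ERCC spike-in, a set of synthetic RNAs added to each sample, were lower in cKO. Per ERCC read there were 334 ± 42 mapped endogenous reads in WT and 233 ± 32 in cKO (SD, n = 3), or 69.8% of WT, a log2 ratio of -0.52. All 3 cKO libraries lay below all 3 WT libraries, and the exact permutation test, two-sided, gave p = 0.1, the smallest value that 3 against 3 libraries allow. ERCC reads made up 0.280 ± 0.036% of reads in WT and 0.397 ± 0.049% in cKO, and 92.8 ± 0.3% and 91.8 ± 0.7% of reads were mapped. The number of oocytes and the amount of spike-in per tube are not stated in the sources used here, so the ratio is per library and not per oocyte.

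The fold change between genotypes varied with the annotated exonic length of genes and with their abundance across the whole transcriptome. In the tenth of genes with the shortest exonic length the median log2 fold change was 0.27, with 30.6% of genes called higher and 9.19% lower, and in the tenth with the longest it was -0.21, with 12.1% higher and 28.5% lower. The slope of log2 CPM on log2 length, relative to the mean of all libraries, was 0.074 ± 0.052 in WT and -0.074 ± 0.021 in cKO (SD, n = 3), with no overlap between the genotypes (exact permutation p = 0.1, the smallest possible). By mean CPM over all libraries, the tenth of genes with the lowest level had a median log2 fold change of 0.29 and the tenth with the highest -0.13, where 30.5% of genes were called lower and 14.7% higher.

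**Figure D4:**
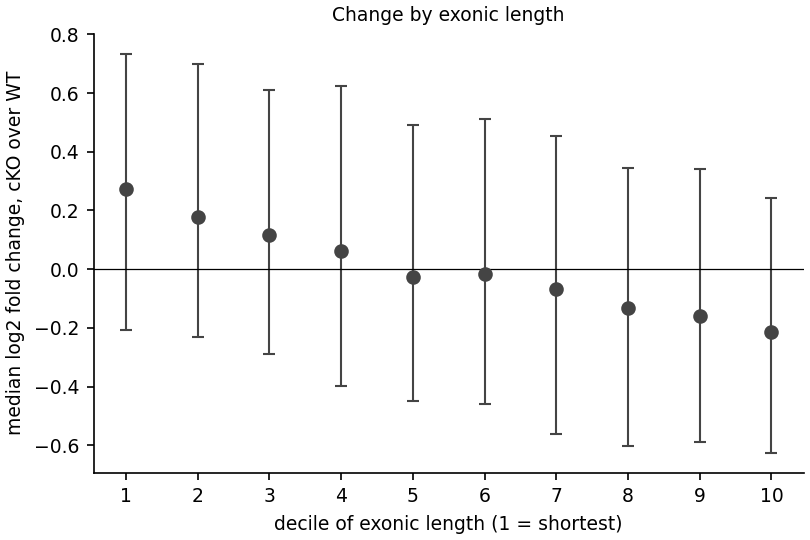
Median log2 fold change (cKO over WT, points) of genes in 10 groups of exonic length from the shortest (1) to the longest (10), with bars from the lower to the upper quartile of the genes. The median went from 0.27 in the shortest group to -0.21 in the longest.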

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

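The length and GC correction, as an alternative processing, and the spike-in share set against all reads were chosen after seeing the data. Spike-in scaling gave 1183 genes higher and 4831 lower, a split set by the scaling itself, of which 1176 and 2838 were among the 2836 and 2838 main calls. At least a 2-fold change left 1440 and 1128 genes and an adjusted p under 0.01 left 1682 and 1818, by the construction of these thresholds. The other normalizations, filters and tools stayed within 1.5 times of both counts, and no gene was called in opposite directions in any of the 16 alternative fits. Library totals alone gave 3450 and 2253. Leaving out 1 library gave 2181 to 2797 genes higher and 2116 to 2709 lower. Nat10 was called in every fit, at -2.62 to -2.88 with a library left out and at -2.67 to -3.17 otherwise. The lists called higher numbered 2 in the main test, 1 after spike-in scaling, 1 after the length and GC correction, 0 with an estimated correlation and 7 with fry; lists called lower numbered 0 except 6 with fry. Fry asks another question; the cause of the other changes was not tested except as given for the ribosomal and oxidative phosphorylation lists. The oxidative phosphorylation median went from 0.38 to -0.029 after spike-in scaling, where that of all genes was -0.39, with a camera adjusted p of 0.184 against 1.94e-05 (0.233 after the length and GC correction). The log2 ratio of endogenous to spike-in reads, -0.52, was -0.44 to -0.64 with a library left out, -0.52 over filtered genes only, -0.39 as the median gene and -0.50 against all reads.

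Of the 142 genes of the naming rule none turned direction when called, 31 lost their call in at least 1 alternative, 20 of them after spike-in scaling, and 15 when a library was left out. Equal replicate numbers showed no clear pairing of the libraries: their deviations from the group means correlated at -0.02, 0.06 and 0.11. Some libraries correlated best with their own number and others did not. With the number as a replicate block 3089 genes were higher and 3110 lower, against 2836 and 2838 without it, so some structure shared by number is not excluded. With that block Nat10 was at -2.77, and 2 lists were called higher and 0 lower. The deposited counts held none of the 13 listed genes of the mitochondrial genome, so an alternative without them was not run. At this depth and with 3 libraries each, an uncalled gene is not shown to be unchanged. The simulated recovery of 22.4% at 1.5-fold does not measure this limit, since only 200 genes were changed there. With 5674 genes called here, the adjusted threshold was reached at larger unadjusted p-values.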

Other observations

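Metabolic genes outside the respiratory chain and several regulatory groups changed gene by gene. Calls were fewer in the glycolysis and TCA cycle list and in the DNA methylation and histone-modifying list than the 40.2% of all tested genes. Of 37 glycolysis, pyruvate and TCA cycle genes 9 rose and 3 fell (4 and 2 adjusted over the list alone), turning to 0 and 15 after spike-in scaling, and 7 and 6 with a median of -0.05 after the length and GC correction. The glucose transporter gene Slc2a1 fell from 124 ± 2 to 64.6 ± 10.6 CPM (SD, n = 3) and Ldha, a lactate dehydrogenase gene, from 6.95 to 2.07 CPM; without cKO replicate 3 the log2 change of Ldha was -2.36 against -1.75. Mdh2, a malate dehydrogenase gene, and Gpi1, the glucose phosphate isomerase gene, rose from 185 to 291 and from 124 to 189 CPM, neither called after spike-in scaling. Of 22 cholesterol synthesis genes 9 rose and 4 fell (9 and 4 adjusted over the list alone; 4 and 5 after spike-in scaling). Pmvk rose from 1.23 to 7.03 CPM and Hmgcs1, which acts at the start of the pathway, fell from 574 ± 43 to 335 ± 62 CPM. Among 46 DNA methylation and histone-modifying genes 7 rose and 6 fell (7 and 6 adjusted over the list alone; 3 and 18 after spike-in scaling, 13 and 9 after the length and GC correction), with a median of -0.05, a mean of 0.04 and a camera direction of down. Suz12, a Polycomb subunit gene, the demethylase gene Kdm6a and the methyltransferase gene Nsd1 fell to 45.2%, 47.1% and 49.3% of WT, while the demethylase gene Kdm5a, whose exons overlap Ccdc77 on the other strand, rose 3.16-fold. Of 17 histone variant genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; 2 and 4 after spike-in scaling, 6 and 4 after the length and GC correction), with H2az1 2.38-fold higher.

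RNA-directed and early embryo genes also split, in a transcriptome where 40.2% of all tested genes were called. The RNA modification list held a smaller share of calls than that. Among 41 other RNA modification genes 9 rose and 6 fell (9 and 6 adjusted over the list alone; 6 and 12 after spike-in scaling). Alkbh5, an m6A eraser gene, and Virma, a subunit of the m6A writer, fell to 56.5% and 53.5% of WT, while the 5-methylcytosine writer gene Nsun2 and the m6A reader gene Ythdf1 rose 2.16-fold each. Of 27 piRNA and small-RNA genes 8 fell and 4 rose (8 and 4 adjusted over the list alone; 11 and 1 after spike-in scaling, 7 and 5 with library totals alone), with Ago2 at 56.7% and Ago3 at 55.8% of WT and Piwil2 2.79-fold higher. Of 13 testable 2-cell and genome activation genes 6 rose and 3 fell (6 and 4 adjusted over the list alone; 5 and 4 after spike-in scaling). Dppa4 rose from 18.96 ± 2.5 to 62.9 ± 7.7 CPM (SD, n = 3), and AU022751 fell from 2845 ± 475 to 1541 ± 138 CPM. The members with near-identical copies, such as the Usp17l genes, are uncertain.

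The tests of the spike-in ratio and the spike-in scale, the other window sizes around Nat10, the windows across the genome, the G-ending codons and the codon test at equal GC content were chosen only after the result was seen, and the length and GC correction was added after the data were seen but with its criterion set before its own result.

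The rise of ribosomal protein and oxidative phosphorylation genes, whose medians relative to the mean of all libraries were -0.17 to -0.36 and -0.12 to -0.28 in the WT libraries against 0.20 to 0.46 and 0.09 to 0.29 in cKO, was set against 2 technical explanations. Removing the length and GC trend took the ribosomal median from 0.58 to 0.3553 (interquartile range 0.11 to 0.60), with 45 members still called higher and 2 lower. The camera adjusted p was 2.6e-05 with the preset correlation and 0.684 with an estimated correlation, and the fry adjusted p was 0.0129. The criterion against that trend as the whole cause was a median above 0 and a camera call. It was met with the preset correlation, and an estimated correlation gave no call. The trend as fitted took away part of the median and not all of it, but whether the rest stands apart from other genes stays open. The oxidative phosphorylation median went from 0.38 to 0.1545 (interquartile range -0.13 to 0.32), with 21 members higher and 5 lower against 40 and 2 before, a camera adjusted p of 0.233 (0.684 with an estimated correlation) and a fry adjusted p of 0.00741, because most of its rise was removed, so for that list the trend is a candidate explanation. Spike-in scaling shifts all genes alike, so the medians of 0.1644 and -0.02896 against -0.39 for all genes still lie above the other genes, and whether either list rose per spike-in molecule stays open, as does an effect of Nat10 loss itself. The real split called 2 lists, 5 of the 10 splits called as many and the highest other called 4; with 0 genes called, 7 of the 9 other splits still called the ribosomal list and 4 the oxidative phosphorylation list with the preset correlation, but each sets 2 libraries of a genotype against 1, so a genotype difference carries into them, and 10 splits are too few for a share under 0.05.

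The lower ratio of endogenous to spike-in reads was set against 3 technical explanations. With every spike-in share moved to the edge of its rounding (a last digit of 0.01%) against the difference, the log2 ratio was still -0.4739 and the genotypes stayed apart, which argues against rounding. Set against all reads, the ratio was -0.5018, which argues against reads lost to mapping. Libraries of one genotype differed by up to 1.284-fold, against 1.43-fold between the genotype means. A different number of oocytes or amount of spike-in per tube cannot be told apart from less poly(A) RNA per oocyte, since neither amount is stated. The libraries were primed with oligo-dT, so the ratio covers the poly(A) RNA that was captured and not all RNA, and capture was not tested. Less poly(A) RNA per cKO oocyte is a hypothesis these data leave open.

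Deleted alleles can carry DNA of another strain around the target, or act on neighbours. Within 10 Mb of Nat10 on chromosome 2, 20 of 65 tested genes (30.8%) were called lower, against 20.1% elsewhere, an odds ratio of 1.772 (95% interval 0.99 to 3.07, Fisher's exact p = 0.0422), which met the criterion set beforehand for a local effect, an exact p under 0.05. In Fisher's exact test the odds ratio was 1.91 within 5 Mb (p = 0.0662) and 1.37 within 20 Mb (p = 0.0448), and 15.4% of the 65 genes were called higher against 20.1% elsewhere. The test was nevertheless read as undecided after a comparison added later, in which 7.04% of 14100 windows of this size across the genome reached as high a share, so a local effect cannot be told apart from the usual variation between regions. The test counts calls and not their size. Agbl2 (90782727 to 90834437) and Tmem87a (120355309 to 120404116), among the 8 largest falls, lie on chromosome 2 outside the 10 Mb window but within 20 Mb. Of the 8 largest rises only Ptgds (25466712 to 25469749) lies on chromosome 2, outside both windows. For Agbl2 and Tmem87a strain DNA or a local effect cannot be told apart from Nat10 loss.

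Acetylcytidine in the wobble position of codons is reported to aid decoding, which led to the hypothesis that transcripts rich in C-ending codons fall when Nat10 is lost. Across 13175 genes, which are not independent replicates, the log2 fold change and the share of codons ending in C had a rank correlation of 0.1139 within bins of length and expression, and codons ending in G gave 0.159. The criterion set beforehand took a value of 0 or above as evidence against the hypothesis, but it did not hold GC content, with which the fold change (0.226) and the C-ending share (0.679) both correlate. In simulated data a fall with C-ending codons gave 0.00645 in these bins once a GC trend was added and -0.421 with GC content held, so the first value cannot decide. The simulated fall had a chosen size and the simulated data held no other changes between genotypes. The value of -0.421 is therefore no measure of what such a fall would give in the real data. With GC content held, C-ending codons gave -0.01236 and G-ending codons 0.062 in 5 bins of each property, and -0.02 and 0.05 in 10 bins, so no clear relation was seen and the hypothesis stays open.

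Grouping the 6 libraries in the 9 other ways into 3 and 3 called 0 genes in each, against 5674 for the genotypes. Each of these groupings puts libraries of both genotypes in each group. The genotype difference then widens the spread within groups and leaves little to call, so the 0 calls decide nothing. Besides, 10 splits are too few for a share under 0.05, and the split as large as the real one was the real one (1 of 10).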
